A study of Mus musculus with 12 samples.

How the data were processed

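RNA was measured in neurons collected by laser capture from 2 neighbouring regions of the mouse brain, the medial (MEC) and lateral (LEC) entorhinal cortex. The mice were female littermates on a C57BL/6 background, aged 2 months. Mutants lacked Naglu, the lysosomal enzyme alpha-N-acetylglucosaminidase that degrades heparan sulfate, and model Sanfilippo syndrome type B. Controls were heterozygous. Per the labels, 500 neurons per region were taken from stained sections 12 µm thick, and their RNA was amplified before labelling. Each region had 3 mutant and control pairs, and each pair was hybridised on 2 Agilent dual-dye arrays with the dyes swapped, which gives 12 arrays. The labels do not say whether MEC and LEC pairs of the same number came from the same mice.

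The deposited scanner files hold, per spot and dye, mean signals and median local backgrounds as raw intensity, with no background subtracted. They also hold intensity values that the authors' scanner software, Agilent Feature Extraction, subtracted for background and normalised between dyes, and a log10 ratio of Cy5 over Cy3. Other deposited columns are flags of 0 or 1, such as saturation or a spot well above background, and carry no unit. Per the file headers the software version was 9.5.1.1, while the submitters' notes name 8.5.1.1. The authors' value table holds log2 ratios per array for 41548 spots, of which 14 were control spots. Its centring and direction are not stated. Probe coordinates are those of build mm8. Gene names were brought up to date with a RefSeq table of assembly GRCm38.p6, used for names alone: of 41174 probes, 23374 were matched by accession, 6733 by symbol and 2919 by an older symbol, and 8148 stayed without a gene name.

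The labels and the value table conflict in 2 ways. Each column of the table was compared with every array over 9166 bright spots, those well above background in at least 20 of 24 readings; each column matched a single array with a correlation of 0.995 to 0.999 in size, and no other array above 0.657. By this match, 5 of the 6 LEC scanner files lie under another LEC sample's name. In replicate 2 of both regions the table's sign is opposite to the labelled dyes. The log2 ratios of the dye-swapped arrays of a pair were correlated across spots after subtracting each spot's mean over all arrays. With arrays assigned by the table, they were then anticorrelated in all 6 pairs, from −0.37 to −0.73. By file name the LEC values were 0.0044, −0.07 and −0.34. Without this subtraction, the table's assignment gave 0.25 in MEC replicate 1 and −0.11 to −0.42 in the other pairs. By file name the LEC values without it were 0.29, 0.13 and 0.14. The table's assignment and direction were used. This choice was made after the files, including the values of Lyz2, had been examined. It was not blind to the outcome, and the direction of replicate 2 is not settled. Each comparison was therefore also run with replicate 2 turned as labelled, with the files and dyes as labelled, and without replicate 2.

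In R 4.3.3 with limma 3.58.1 and data.table (1.17.8), local background was corrected by normexp with an offset of 50, dyes were balanced by loess within each array, and log2 ratios of mutant over control were averaged over the spots of a probe and the arrays of a pair. A probe was kept where it was well above background in at least 4 of the 6 readings of 1 region and genotype. This left 12987 probes. A gene was represented by its probe of highest mean intensity, which gave 10744 genes, of which 9422 carry a gene name. For genes named in the comparisons, other kept probes gave 33 values, of which 19 had the sign of the probe used. The unit of replication is the pair mean, 3 per region. The limma model gave each region a mean and shared the spread over the 6 pairs; tested were the mutant effect in MEC, in LEC, averaged over both regions, and its difference between regions. Levels in MEC and LEC were compared on the mean log2 intensity of both dyes, quantile-normalised between arrays, with 3 pair means per region. Limma's p-values are two-sided, measure the spread between these samples and are adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. If MEC and LEC came from the same mice and pairs of the same number vary together, the p-values of the average over both regions are too small.

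Sets of genes were tested with camera at a preset correlation of 0.01, adjusted over 31 lists. With this preset, camera sets a list's members against the other genes. Its p does not measure how the list's mean varies between pairs. Camera with an estimated correlation and fry were run beside it. Of these lists, 7 hold cell type markers (excitatory neurons, inhibitory neurons, microglia, astrocytes, oligodendrocytes, vessels, and blood with choroid plexus and meninges), since laser capture can take in neighbouring cells. The comparisons, filters, tests, lists, alternative settings and the rule for naming genes were fixed before the data were examined; the assignment of arrays was not. The rule names Naglu, the 10 largest rises and falls among genes that pass and move the same way in all pairs, the 5 smallest p-values of a direction where fewer than 5 pass, and up to 4 members of each list that passed or concerns the lysosome, heparan sulfate, tau or a cell type. The genes printed are a selection of these, and some genes are not reported here. The procedure was tested on simulated data, with normal noise drawn independently for each gene and pair at the measured spread. The simulation held no correlation between genes, no replicate of uncertain direction and no scan day. Each run also held many changed genes, some by 2 log2 units, which makes the adjusted threshold easier to pass. The shares below therefore hold for such data and need not hold for these arrays, least of all for levels. In these arrays Lyz2, at 1.79 in MEC and 1.77 in LEC, did not pass limma (adjusted p 0.428 and 0.916). A count of 0 genes thus does not exclude changes of the sizes simulated. Of genes changed by 1 log2 unit, limma recovered 85.2% in MEC, 81.1% in LEC, 93.3% over both regions and 97.6% for levels. At 0.5 log2 units, nearer to most ratios reported, these were 49.6%, 53.3%, 71.6% and 86%, and 5.85%, 5.95%, 5.43% and 5.32% of all calls were false.

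Signal over background limits the precision, as does the number of arrays. Per array, 48.2% to 67.9% of spots were well above background in Cy3 and 14.8% to 30.4% in Cy5. The arrays were scanned on 2 days, MEC on 1 at 10 µm per pixel and LEC on the other at 5 µm, so no day holds both regions. Each array was on its own slide, so neither slide nor day could serve as a block. Alternatives were 27 settings fixed at the outset, of background, normalisation, filter, moderation, units, threshold, set test and left-out pairs, and 3 settings added after seeing the data for the conflict described above. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.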

Results

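The data are 12 dual-dye arrays of laser-captured entorhinal neurons from Naglu-null mice and heterozygous littermates, with 3 pairs for MEC and 3 for LEC, each pair on 2 dye-swapped arrays. Per array, the median mean signal was 67 to 92.5 in Cy3 and 44.4 to 54.9 in Cy5, and 48.2% to 67.9% of spots were well above background in Cy3. The ratios are log2 of mutant over control, and SE is limma's standard error with n = 3 pairs per region unless stated. For replicate 2 of both regions, the sign of these ratios follows the authors' value table, which opposes the labelled dyes, so each comparison is also given with replicate 2 turned as labelled.

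Naglu, the disrupted gene, had a log2 ratio of 0.03 ± 0.07 (SD, n = 3) in MEC and 0.01 ± 0.05 (SD, n = 3) in LEC at its brighter probe (build mm8, chromosome 11, 100893407 to 100893466). By pair the ratios were −0.04, 0.09 and 0.05 in MEC and 0.01, −0.04 and 0.06 in LEC. The probe was well above background in 12 of 12 Cy3 readings and 0 of 12 Cy5 readings, below the filter, and the gene's other probe (100889169 to 100889228) in 0 of 24. Where either probe lies relative to the disrupted part of the gene is not known, and the control carries a single intact copy, so these values check neither genotype nor labels.

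In MEC, the comparison of mutant with control asked which transcripts differ in neurons that lack Naglu, and Lyz2, the lysozyme gene of macrophages and microglia, had the highest ratio among the genes with the smallest p (probe accession NM_017372, build mm8, chromosome 10, 116681504 to 116681563). Its ratios were 1.67, 1.80 and 1.90 in the 3 pairs, a mean of 1.79 (SE 0.22) or 3.45-fold. With Agilent's processed signals it was 2.73 or 6.65-fold, so the size depends on the processing. Ctss, the lysosomal protease cathepsin S of microglia, stood at 0.78 (SE 0.19), and Trem2, a microglial surface receptor, at 0.40 (SE 0.09). On the other side stood 9530080O11Rik at −0.59 (SE 0.07) and the transcription factor gene Arid5b at −0.57 (SE 0.07). Another Arid5b probe read −0.21. Tfam, which packages and transcribes mitochondrial DNA, read −0.54 (SE 0.08), and the cytochrome c oxidase subunit Cox8a −0.38 (SE 0.06). None of these passed limma's adjustment over 10744 genes: Lyz2, 9530080O11Rik and Arid5b had the smallest adjusted p, 0.428.

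Of the 31 lists in MEC, 6 passed camera, and none of the 6 held with an estimated correlation or with fry. The 67 measured genes of the mitochondrial respiratory chain and ATP synthase had a mean of −0.079, 51 of them under 0, and fell as a list (adjusted p = 1.01e-05, adjusted p = 0.293 with an estimated correlation). Over all genes 0 members passed, and 1 did adjusted over the list alone, Cox8a. Ndufa7, a subunit of respiratory complex I, read −0.27. The 20 measured microglial and macrophage markers rose as a list (mean 0.18, median 0.03, 15 above 0, adjusted p = 1.71e-05, adjusted p = 0.301 with an estimated correlation). Of these markers 0 passed over all genes and 3 adjusted over the list alone. Genes of amyloid precursor processing and Alzheimer risk (mean 0.079, median 0.036, 13 of 16 above 0, adjusted p = 0.00395, adjusted p = 0.293 with an estimated correlation) rose as a list. Aplp2, a relative of the amyloid precursor, read 0.33, although its other probe read −0.03. This list shares Trem2 with the microglial list. Oxidative stress defence genes fell as a list (mean −0.065, 22 of 25 under 0, adjusted p = 0.00644, adjusted p = 0.293 with an estimated correlation). The glutathione peroxidase Gpx4 read −0.24 and thioredoxin, Txn1, −0.15. Cathepsins and their inhibitors (mean 0.087, median 0.028, 9 of 13 above 0, adjusted p = 0.022, adjusted p = 0.425 with an estimated correlation) rose as a list, with Ctsb at 0.34. So did ganglioside metabolism (mean 0.064, 9 of 12 above 0, adjusted p = 0.0401, adjusted p = 0.301 with an estimated correlation), with the sialyltransferase St8sia5 at 0.30. Another St8sia5 probe read 0.03. In these last 4 groups 0 genes passed, over all genes or adjusted over the list alone. The other 25 lists had adjusted p from 0.0571 to 0.978.

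Further MEC genes with small unadjusted p were Fam168b at 0.44 (SE 0.09) and Sccpdh at 0.38 (SE 0.09). On the other side was Fbxo2, a ubiquitin ligase subunit that binds glycoproteins, at −0.71 (SE 0.15) with other probes at 0.03 and −0.07. The lysosomal thioesterase Ppt1 read 0.17, with other probes at −0.00091, −0.02 and 0.03. Markers of other cells gave 0.25 for the myelin gene Mobp and 0.18 for the endothelial receptor Flt1. With processed signals Mobp read 0.84 and Flt1 0.65, so the size depends on the processing here too. No gene passed limma in MEC (0 of 10744), and 118 had an unadjusted p under 0.05 where chance gives 537.2. Of all genes, 14.5% had 1 sign in all 3 pairs where chance gives 25%. Turned as labelled, replicate 2 left 0 genes passing and 1179 at an unadjusted p under 0.05, and Lyz2 at 0.59. Of the 6 lists only the mitochondrial one then passed (mean −0.12, adjusted p = 2.13e-05), and the other 5 had adjusted p from 0.549 to 0.755, with the microglial mean at 0.087 (adjusted p = 0.738). Without LEC replicate 2, whose spread enters the shared estimate, Lyz2 passed in MEC (adjusted p = 0.0187; range over its alternatives 0.000347 to 1.00). The lower end of this range came from the 12 arrays as units, where the dye-swapped duplicates of a pair enter separately. Without replicate 2 of both regions, oxidative stress defence (adjusted p = 0.0974), cathepsins (adjusted p = 0.140) and gangliosides (adjusted p = 0.184) no longer passed, nor did they without any single MEC pair. Without MEC replicate 3 the mitochondrial list had a mean of 0.02 and 1 list passed, the microglial one, which did so without each of the 6 pairs.

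In LEC, where the comparison asked the same of the neighbouring region, Lyz2 again had the highest ratio among the genes with the smallest p, 1.77 (SE 0.22) or 3.41-fold, with 1.17, 2.50 and 1.64 in the 3 pairs, and 2.39 or 5.25-fold with processed signals. Ctss stood at 0.84 (SE 0.19), Trem2 at 0.39 (SE 0.09) and the complement chain C1qc at 0.38 (SE 0.09). The major histocompatibility heavy chain H2-K1 read 0.41 (SE 0.09), with another probe at 0.04. Blnk, an adaptor of B-cell receptor signalling, read 0.42 (SE 0.07) and the metalloprotease gene Amz1 0.34 (SE 0.06). Under 0 were Ust, which sulfates uronic acid in glycosaminoglycans, at −0.39 (SE 0.10) and Acyp2 at −0.31 (SE 0.08). Kalrn, a regulator of dendritic spines, read −0.30 (SE 0.07) with another probe at 0.06. Tmem42 stood at −0.24 with another probe at 0.14, and the steroid reductase Srd5a1 at −0.22. None of these passed limma (smallest adjusted p 0.916, for Lyz2).

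Of the lists in LEC, 7 passed camera, and none held with an estimated correlation or with fry. Mitochondrial respiratory chain and ATP synthase genes again fell as a list (mean −0.079, 58 of 67 under 0, adjusted p = 7.27e-08, adjusted p = 0.467 with an estimated correlation). The members included Ndufb4 at −0.21, Ndufab1 at −0.20 and cytochrome c, Cycs, at −0.19 with other probes at 0.0012 and −0.05. Microglial and macrophage markers rose as a list (mean 0.19, median 0.04, 15 of 20 above 0, adjusted p = 0.000752, adjusted p = 0.494 with an estimated correlation). Of these, 0 passed over all genes and 4 adjusted over the list alone. Cathepsins and inhibitors (mean 0.11, median 0.028, 9 of 13 above 0, adjusted p = 0.0449, adjusted p = 0.494 with an estimated correlation) rose as a list. The list held 1 gene passing adjusted over the list alone, and Ctsb read 0.30. All 6 measured interferon response genes were above 0 (mean 0.096, adjusted p = 0.0102, adjusted p = 0.467 with an estimated correlation), with the macrophage factor Irf8 at 0.14 near background (5 of 12 LEC readings well above it). Immediate early genes had a mean of 0.10 with 14 of 20 above 0 (adjusted p = 0.0166, adjusted p = 0.679 with an estimated correlation), among them Ier5 at 0.39. Astrocyte markers had a mean of 0.098 with 13 of 16 above 0 (adjusted p = 0.0318, adjusted p = 0.807 with an estimated correlation). Markers of cortical layers and the hippocampal formation had a mean of −0.14 with 17 of 24 under 0 (adjusted p = 0.00593, adjusted p = 0.494 with an estimated correlation). Apart from the microglial and cathepsin genes counted, 0 members of these 7 lists passed, over all genes or adjusted over the list alone. Among the other 24 lists (adjusted p 0.118 to 0.997), antigen presentation and complement each held 1 such gene adjusted over the list alone.

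LEC replicate 2 stood apart in markers of other cells. The astrocyte list averaged 0.52 in that pair against −0.04 and −0.19 in the others. Blood, choroid plexus and meningeal markers averaged 0.76 against −0.31 and −0.42. Without that pair the astrocyte list had a mean of −0.11, and the calls of microglial markers (mean 0.11, adjusted p = 0.227), interferon response (0.067, adjusted p = 0.277) and cathepsins (0.029, adjusted p = 0.808) were lost. The cathepsin means by pair were 0.022, 0.28 and 0.035. Immediate early genes stood at 0.25, −0.16 and 0.21, and without replicate 2 at 0.23. By camera their call was lost without LEC replicate 1 (mean 0.025, adjusted p = 0.676) and without LEC replicate 3 (mean 0.047, adjusted p = 0.295). Plcz1, a phospholipase known from sperm, was well above background in 5 of 6 mutant readings and 0 of 6 control readings in LEC, at least 1.20-fold higher in mutant by its background bound. With replicate 2 turned as labelled the readings were 3 and 2, and this bound no longer holds. By limma 0 of 10744 genes passed in LEC, 164 had an unadjusted p under 0.05, and 17.2% had 1 sign in all 3 pairs. With replicate 2 turned as labelled, 0 genes passed, 1064 had an unadjusted p under 0.05, Lyz2 read 0.10 and Ctss −0.10. This turn reversed the list means of microglial markers (−0.04), cathepsins (−0.08), interferon response (−0.03) and astrocytes (−0.24). The astrocyte list then passed in the opposite direction (adjusted p = 0.000197), and immediate early genes still passed (mean 0.19, adjusted p = 0.00404). The other 5 of the 7 lists had adjusted p from 0.145 to 0.786, among them the mitochondrial list at −0.025 (adjusted p = 0.409). Without LEC replicate 3, 3 lists passed, and the cortical layer list read −0.061 (adjusted p = 0.576), with −0.29 in that pair against −0.08 and −0.05. Of the 7 lists, the mitochondrial one alone passed without each of the 6 pairs. Without replicate 2 of both regions the microglial, interferon and cathepsin lists had adjusted p of 0.276, 0.284 and 0.808.

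**Figure D1:**
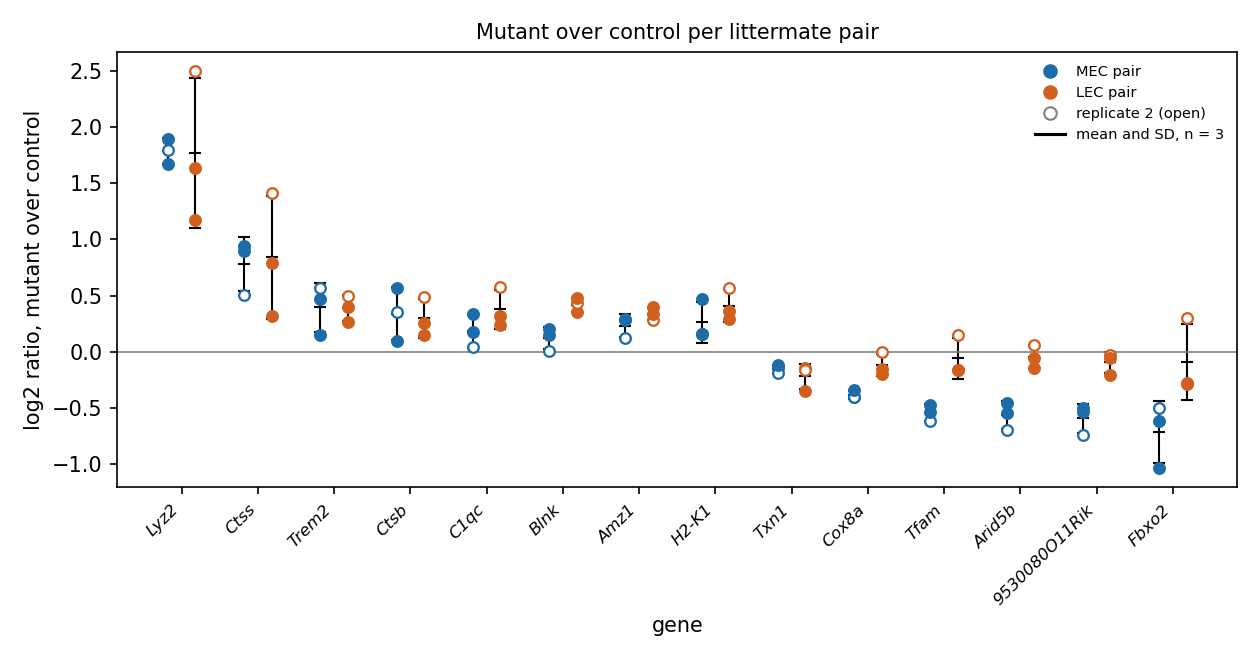
Log2 ratio of mutant over control (vertical axis) for 14 named genes in each littermate pair; blue points are MEC pairs, orange points LEC pairs, open points replicate 2 in the direction of the authors' value table, and bars the mean and SD of 3 pairs. Lyz2 lies between 1.17 and 2.50 in all 6 pairs, and would lie at −1.80 and −2.50 in replicate 2 if that replicate were turned as labelled.

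Averaged over MEC and LEC, to find effects of the genotype shared by the regions, Lyz2 stood at 1.78 (SE 0.15, n = 6 pairs) or 3.43-fold, with the mutant dye brighter on 12 of 12 arrays, or 8 of 12 with replicate 2 turned as labelled. Ctss averaged 0.81 (SE 0.14) and was likewise higher in mutant on 12 of 12 arrays (8 of 12 turned), as were Ctsb at 0.32 (SE 0.08) and the sialyltransferase St3gal2 at 0.16 (SE 0.05). Trem2 averaged 0.39 (SE 0.07), C1qc 0.28 (SE 0.06) and Amz1 0.28 (SE 0.05). With processed signals Lyz2 read 2.56 or 5.91-fold, Ctss 1.08, Trem2 0.80, C1qc 0.65 and Amz1 0.53. Means of other genes were Blnk 0.27 (SE 0.05), Aplp2 0.24 (SE 0.08) and Ppt1 0.16 (SE 0.06). Other probes of Ppt1 read 0.02, −0.02 and 0.02. Lower values were those of 9530080O11Rik at −0.34 (SE 0.05), Arid5b at −0.31 (SE 0.05, another probe at −0.15) and Tfam at −0.30 (SE 0.06). Cox8a stood at −0.25 (SE 0.04), Ndufa7 at −0.19 (SE 0.06) and Txn1 at −0.19 (SE 0.05), which was under 0 in 6 of 6 pairs. Lyz2 came closest to the threshold without passing it (adjusted p = 0.0922; range over its alternatives 3.12e-06 to 1.00). The lower end came from the 12 arrays as units, where the dye-swapped duplicates of a pair enter separately. The next lowest adjusted p from limma was 0.00884, without LEC replicate 2.

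Over both regions 8 lists passed camera, and none held with an estimated correlation or with fry. Mitochondrial genes fell as a list (mean −0.079, 55 of 67 under 0, adjusted p = 1.47e-10, adjusted p = 0.289 with an estimated correlation). By pair the means were −0.02, 0.06 and −0.28 in MEC and −0.09, −0.08 and −0.07 in LEC. Over these 6 pairs the exact sign-flip p was 0.094 (adjusted over the 31 lists 0.484). Microglial and macrophage markers rose as a list (mean 0.18, median 0.04, adjusted p = 1.19e-05, adjusted p = 0.289 with an estimated correlation). Of these, 0 passed over all genes and 5 adjusted over the list alone. Their mean was above 0 in 6 of 6 pairs (exact sign-flip p = 0.0312, adjusted over the 31 lists 0.242). Lyz2 carried much of it, since without Lyz2 the mean was 0.10, and 0.0072 with replicate 2 turned as labelled. Lists whose mean also lay above 0 in 6 of 6 pairs were cathepsins and inhibitors (0.10, median 0.028, adjusted p = 0.00755, adjusted p = 0.289 with an estimated correlation, with 2 adjusted over the list alone) and amyloid precursor processing and Alzheimer risk (0.073, median 0.042, adjusted p = 0.00528, adjusted p = 0.289 with an estimated correlation, with 1 adjusted over the list alone). The cathepsin mean rests largely on Ctss and Ctsb, and Ctss and Lgmn are also in the microglial list. Trem2, at 0.39, is in both the amyloid and the microglial list. Aplp2, in the amyloid list, read 0.24 with another probe at 0.02. Ganglioside metabolism was another such list (0.053, adjusted p = 0.0363, adjusted p = 0.289 with an estimated correlation, with 0 adjusted over the list alone). Immediate early genes rose as a list (mean 0.091, 17 of 20 above 0, adjusted p = 0.00528, adjusted p = 0.497 with an estimated correlation). Markers of cortical layers and the hippocampal formation (mean −0.10, adjusted p = 0.00528, adjusted p = 0.289 with an estimated correlation) and oxidative stress defence genes (mean −0.044, adjusted p = 0.00546, adjusted p = 0.289 with an estimated correlation) fell as lists. In these, the immediate early and the mitochondrial lists 0 genes passed adjusted over the list alone. With replicate 2 turned as labelled only the mitochondrial list of the 8 passed (mean −0.072, adjusted p = 0.000242). The other 7 had adjusted p from 0.0746 to 0.813, and the microglial list read 0.024 (adjusted p = 0.808). Without replicate 2 of both regions cathepsins (adjusted p = 0.341) and gangliosides (adjusted p = 0.127) no longer passed, while the microglial list did (adjusted p = 0.0198). The microglial and amyloid lists, which share Trem2, passed without each of the 6 pairs, and the ganglioside list in 0 of these 6 settings. Immediate early genes passed in 2 of the 6 settings, cathepsins in 4, and the cortical layer and oxidative stress lists in 5 each. The cortical layer call was lost without LEC replicate 3 (mean −0.063, adjusted p = 0.193). The mitochondrial call was lost without MEC replicate 3 (mean −0.030, adjusted p = 0.0512).

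The groups closest to the missing enzyme gave no call. Over both regions, heparan sulfate synthesis and remodelling averaged −0.0019 with a median of 0.005 (13 of 25 genes above 0), lysosomal hydrolases and activators 0.029 (18 of 25 above 0), and lysosomal membrane and v-ATPase genes 0.021. Means were −0.0093 for tau with its kinases and phosphatases and 0.00063 for autophagy (median −0.0079). They were −0.00096 for ubiquitin and proteasome (median 0.0067), 0.035 for cholesterol synthesis and uptake, 0.027 for the unfolded protein response and 0.016 for apoptosis. Neuronal groups averaged 0.013 for synaptic vesicle release, 0.013 for postsynaptic receptors, −0.02 for cytoskeleton and axonal transport, −0.036 for excitatory and 0.031 for inhibitory neuron markers, and ribosomal proteins −0.025. Immune groups averaged 0.047 for complement, 0.055 for antigen presentation (each with 1 gene passing adjusted over the list alone), 0.048 for interferon response and 0.0093 for cytokines. Among other cell types the means were 0.047 for astrocytes, 0.016 for oligodendrocytes, 0.023 for vessels and −0.025 for blood, choroid plexus and meninges. These 23 lists had camera adjusted p from 0.0665 to 0.997. Mean, median and test differed in sign for 5 lists in MEC, 3 in LEC, 3 over both regions, 10 for the difference between regions and 9 for levels, and 0 of these lists passed.

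Over both regions 0 of 10744 genes passed limma, 233 had an unadjusted p under 0.05, and 1.86% had 1 sign in MEC's 3 pairs and the same in LEC's, where chance gives 3.125%. Turned as labelled, replicate 2 left 0 passing, 1274 at an unadjusted p under 0.05, Lyz2 at 0.35 and Ctss at 0.17; without replicate 2 these were 0, 680, 1.59 and 0.74. Without LEC replicate 2 alone, Lyz2 passed at 1.60 (adjusted p = 0.00884), and without LEC replicate 3, 5 lists passed.

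**Figure D2:**
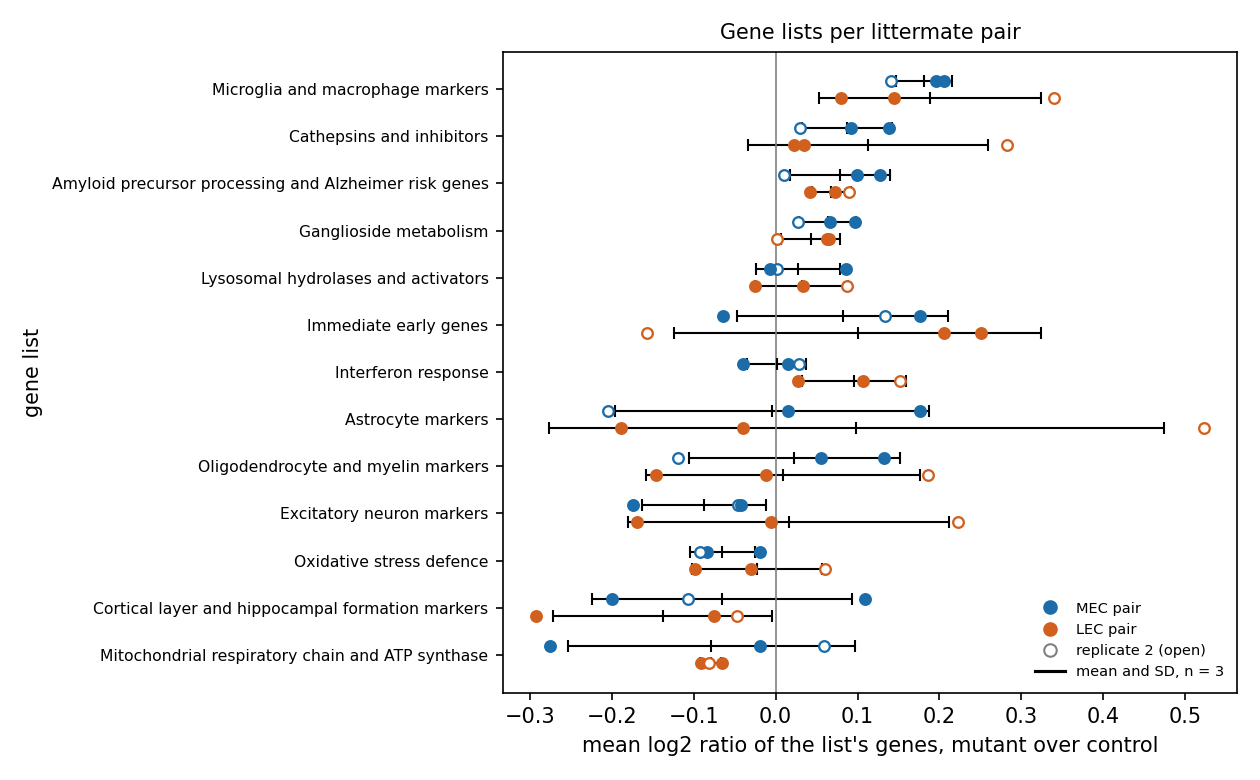
Mean log2 ratio of mutant over control (horizontal axis) over the measured genes of 13 lists in each pair; blue points are MEC pairs, orange points LEC pairs, open points replicate 2 in the direction of the authors' value table, and bars the mean and SD of 3 pairs. Microglial and macrophage markers lie above 0 in all 6 pairs in this direction, the mitochondrial list under 0 in 5 of 6, and the astrocyte list reaches 0.52 in LEC replicate 2.

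The difference between the mutant effects of MEC and LEC asked whether the regions respond unequally. Among the genes with the smallest p, MEC lay above LEC for Ust by 0.47 (SE 0.14) and Srd5a1 by 0.39 (SE 0.09). It did so for the liprin gene Ppfibp2 by 0.35 (SE 0.11), Acyp2 by 0.34 (SE 0.11) and the fatty acid ligase Acsl1 by 0.28 (SE 0.09). With MEC under LEC stood Arid5b at −0.52 (SE 0.10, another probe at −0.13), 9530080O11Rik at −0.50 (SE 0.11) and the cytoskeletal adaptor Pdlim1 at −0.49 (SE 0.14). Others were Tfam at −0.48 (SE 0.12) and the tetraspanin Tspan33 at −0.38 (SE 0.11) with another probe at 0.0034. With processed signals Pdlim1 read −1.58 and Ppfibp2 1.28. Among lists, interferon response (mean −0.094) and astrocyte markers (mean −0.10) had the smallest adjusted p, 0.400 each (0.996 with an estimated correlation), and 0 of 31 passed camera or fry. No gene passed limma (0 of 10744, smallest adjusted p 1.00), and 57 had an unadjusted p under 0.05. With replicate 2 turned as labelled, 956 had an unadjusted p under 0.05 and 1 passed. Tfam then read 0.03 and 3 lists passed, and without replicate 2 the count of lists was 4. Without a single pair 0 genes and 0 to 3 lists passed.

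Shared between the regions were 0 genes, since 0 passed in either by limma (118 in MEC and 164 in LEC at an unadjusted p under 0.05). Across genes, with replicate 2 in the direction of the authors' value table, the mean ratios of MEC and LEC correlated with Pearson's r = 0.35 and Spearman's rho = 0.26. The value with replicate 2 turned as labelled is not reported here, so these correlations rest on an unsettled direction. Genes are not independent replicates, so no p is given. Single pairs went apart, as MEC replicates 2 and 3 correlated at −0.58 across genes and LEC replicates 2 and 3 at −0.47. Between the regions, MEC replicate 3 and LEC replicate 1 reached 0.54, and all other combinations lay from −0.24 to 0.25.

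Expression levels, compared between the captures of MEC and LEC with both genotypes entering equally, differed widely. Higher in MEC were Plxdc1 by 1.79 (SE 0.07, adjusted p = 2.87e-05) and the synapse organiser Cbln1 by 1.79 (SE 0.43). So were the secreted neuronal protein gene Lgi2 by 1.67, Fndc5, the irisin precursor, by 1.55, the cation exchanger Slc24a2 by 1.54, and the transcription factor gene Lef1 by 1.48. Other probes of Lgi2 and Fndc5 read 0.48 and 1.05. Lower in MEC were Penk, the enkephalin precursor, at −2.52 (SE 0.29, adjusted p = 0.00143), the slow myosin heavy chain Myh7 at −1.92 and Zcchc12 at −1.76. Lower too were the protocadherin Pcdh8 at −1.58, Grn, the progranulin gene, at −1.40, the neuronal nitric oxide synthase Nos1 at −1.30, and the nuclear receptor Nr2f2 at −1.26 with other probes at 0.03 and −0.69. Kdm8, Septin6 and Lnx1 were higher in MEC by 1.24 each, Lnx1 with other probes at 0.04 and −0.01. Vat1l (−1.65, other probe 0.01), Eaf2 (−1.22) and Tspan33 (−1.21, other probe −0.11) were lower. In all, limma called 2757 of 10744 genes, 1276 higher in MEC and 1481 lower.

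Genes of the mitochondrial respiratory chain and ATP synthase were the single list to pass camera for levels (mean 0.16, 50 of 67 above 0, adjusted p = 9.62e-05, adjusted p = 0.605 with an estimated correlation, and 0.0199 by fry). With median centring in place of quantile normalisation the mean was −0.34 and the call was lost (adjusted p = 0.468). Over all genes 24 members passed higher in MEC and 2 lower, and adjusted over the list alone 28 and 4. Among them were Cox5a by 0.87, Ndufs4 by 0.85, Ndufs1 by 0.64 and Atp5j2 by 0.59, and with median centring these read 0.22, 0.35, 0.19 and 0.01. Among neuron markers, the layer marker Neurod6 was higher in MEC by 1.16, and the interneuron genes Pvalb by 0.55 and Gad1 by 0.31, while Nrgn, a postsynaptic calmodulin-binding protein, read −1.16. With processed signals these 4 genes read 2.53, 1.62, 0.61 and −1.21. Another Gad1 probe read 0.19. Among myelin genes Mobp was higher by 0.67, and Mbp read −0.96 at its brighter probe and 1.06 at its other. In the lysosomal and heparan sulfate lists the synthesis gene Extl2 was higher by 0.72 and the proteoglycan core Gpc3 lower, at −0.53, a size set by background, since 4 of its 12 MEC readings were well above it. The pump subunit Atp6v1g1 was higher by 0.81 with another probe at −0.10, and the acid lipase Lipa lower at −0.57. The tau kinase Mapk10 was higher by 0.68 with another probe at 0.19. With median centring Gad1, Mapk10 and Atp6v1g1 read 0.05, 0.11 and 0.21 and no longer passed, nor did Cbln1, Kdm8, Lnx1, Ndufs1 and Atp5j2.

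MEC arrays were scanned on 1 day and LEC arrays on another at a different resolution, so region and scan day cannot be told apart for any level. Median centring moved the median difference of all genes from −0.01 to −0.19 and called 5814 genes, 158 higher in MEC and 5656 lower, so the split between higher and lower depends on the scaling. Calls numbered 535 from control channels, 385 from mutant channels, 725 without replicate 2, and 1719 and 1762 without MEC replicate 1 and LEC replicate 2.

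**Figure D3:**
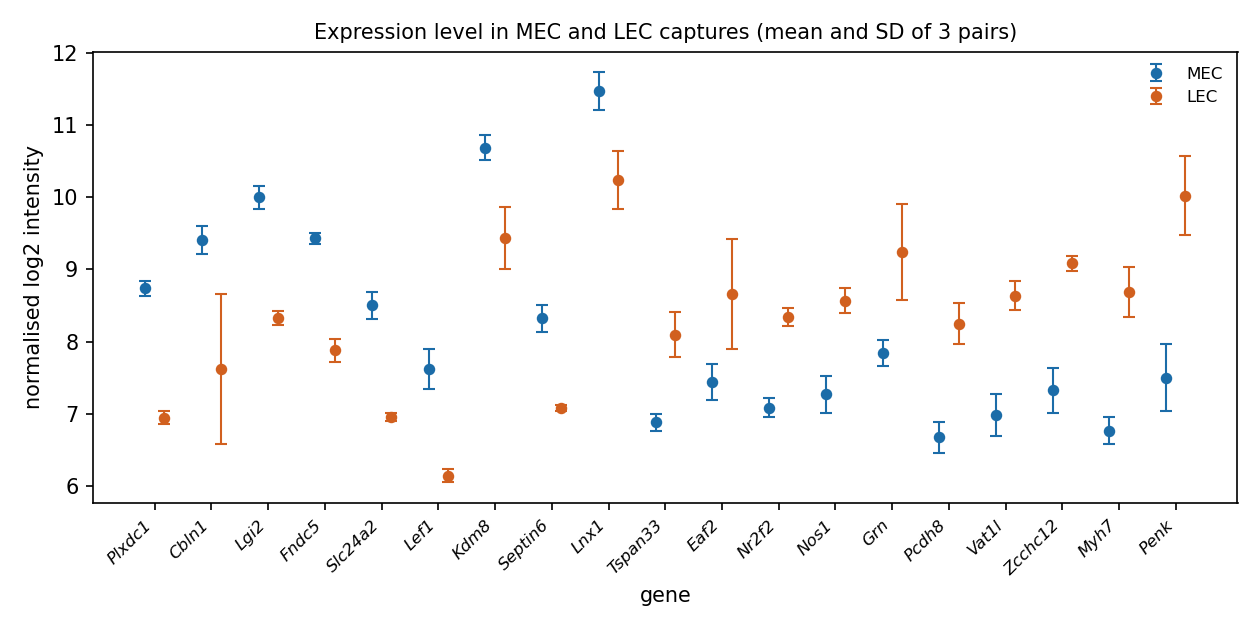
Normalised log2 intensity (vertical axis, not starting at 0) of 19 genes in MEC captures (blue) and LEC captures (orange); points are means of 3 pair means and bars their SD. Genes from Plxdc1 to Lnx1 are higher in MEC and from Tspan33 to Penk lower, with Penk at −2.52 log2 units. The arrays of the regions were scanned on different days.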

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

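The tests on replicate 2, on microglial transcripts and on scan day were chosen only after the results were seen, and the counts over other splits of the samples before. In 5 of the printed genes every MEC pair lay on 1 side of 0 and every LEC pair on the other, so the mutant effect of MEC minus that of LEC stood out by sign alone. The difference was 0.39 for Srd5a1 (0.16 to 0.19 in MEC, −0.31 to −0.11 in LEC), 0.24 for Cycs, 0.35 for Ppfibp2, −0.49 for Pdlim1 and 0.14 for Gpc3, with replicate 2 in the direction of the authors' value table. For Gpc3, 4 of 12 MEC readings were well above background, so its MEC ratios lie near the floor. Of 10744 genes 87 showed this pattern, where chance gives 335.75. The sign pattern itself was not tested, and limma's test of the difference did not pass for these genes (adjusted p = 1.00 each). Groups of 3 pairs are too small for a test of single outlying pairs.

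Replicate 2 runs 1 way in the authors' value table and the other way in the labelled dyes of both regions. If the labels were wrong, at least 15 of the 20 genes with the smallest p over replicates 1 and 3 should keep their sign in replicate 2 of both regions as the table gives it, and if the table were wrong, at least 15 should have the opposite sign. The counts were 7 and 3, where chance gives 5 each, with 16 keeping their sign in MEC and 8 in LEC, so neither explanation is excluded. Other values lean toward the labels, as replicate 2 in the table's direction correlated with replicate 3 at −0.58 in MEC and −0.47 in LEC and turning it raised genes at an unadjusted p under 0.05 from 233 to 1274 over both regions (537.2 by chance), but with replicate 1 it correlated at 0.10 and −0.09, and 3 other sign patterns gave still more genes, so the direction stays open. Lyz2 was at least 1.17 in the other 4 pairs and would be −1.80 and −2.50 in replicate 2 if the labels were right, but it had been seen when the direction was chosen and decides nothing, and every signed mutant value that includes replicate 2 depends on this choice.

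In the direction of the authors' value table Lyz2 read higher in mutant captures of neurons and the microglial list had a mean of 0.18 (median 0.04, 15 of 20 markers above 0), while 0 genes passed limma and the list read 0.024 with replicate 2 turned as labelled (adjusted p = 0.808). A lower share of neurons would raise markers of all other cells alike, and the microglial list lay above the mean of the astrocyte, oligodendrocyte and vessel lists in 6 of 6 pairs, but in 4 of 6 with replicate 2 turned and in 5 of 6 without Lyz2, so this explanation stays open. More microglia of unchanged content should raise the other markers as much as Lyz2, and the 10 others bright in at least 20 of 24 readings had a median of 0.10 against 1.78 (0.18 against 2.56 with processed signals), which leans against it. It may still account for part and cannot be told apart from a change inside cells, since 2 of the 10 reached a mean log2 intensity of 7, among them Ctss (8.03, ratio 0.81), and the others were dimmer, at 6.21 to 6.75. The genotype stays open and untested, since the exact sign-flip p of Lyz2, 0.03125 (the smallest that 6 pairs can give, 0.656 with replicate 2 turned), comes from a gene picked for its small p and a direction chosen after its values were seen.

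Genes at another level in MEC than in LEC captures (2757) may reflect the region, or scan day and scan resolution. The number of scan days that hold both regions is 0, with MEC scanned on 1 day at 10 µm per pixel and LEC on another at 5 µm, so these explanations cannot be told apart. The biological difference between the regions stays open and untested.

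Other splits of the samples were counted beside each gene count from limma, where genes at an unadjusted p under 0.05 numbered 118 in MEC, 164 in LEC, 57 for the difference and 233 over both regions, against 537.2 by chance. Turning the sign of some pairs gave, for the 3 MEC pairs, 4 of 4 patterns with as many genes as the real 0 (highest other 0), and for LEC likewise 4 of 4 (real 0, highest other 0), patterns too few to test chance. Over both regions 32 of 32 patterns gave as many as the real 0, the highest other being 2, and as any count reaches 0 this says nothing about chance. There, other patterns gave up to 1823 genes at an unadjusted p under 0.05 against 233, which points to a structure shared by some samples with opposite signs. For the difference between regions 10 of 10 splits gave as many (real 0, highest other 0), and for levels 1 of 10 (real 2757, highest other 0), in both cases splits too few to test chance.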

How the results depend on the processing

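The settings for labelled dyes, for file names and without replicate 2 were added after seeing the data. Under the 27 settings planned before, the genes named in the comparisons above, other than Naglu, kept their sign in all 1492 values. Of these values 38 fell behind the threshold and 12 passed it anew. In the 3 added settings 6 of 290 values reversed. The kept signs are no measure of stability, since these genes were picked for a small p or a large change in the same data. Several settings also leave the ratio unchanged, as for Lyz2, at 1.78 over both regions with no filter, with all 24 readings above background and with the replicate block. The genes under other observations, and Cycs and Gpc3 for the difference, were not counted. With 0 genes in the main results, both regions gave 1 gene, Lyz2, with processed signals, with all 24 readings above background (4970 genes tested), at adjusted p 0.10 and with ratios scaled between arrays, and 2 (Lyz2 and Ctss) with the 12 arrays as units (dye as covariate, pair as random block, correlation 0.556). MEC gave 1, Lyz2, from its own pairs alone and 4 with the 12 arrays (Lyz2, Arid5b, 9530080O11Rik and the transcript ENSMUST00000035012), and LEC 1, Lyz2, with the 12 arrays. Level calls were 5814 with median centring, 535 from control channels, 385 from mutant channels and 725 without replicate 2, against 2757. With median centring 2 lists passed for levels, and the mitochondrial list had a mean of −0.34. With an estimated correlation 0 lists passed in MEC, LEC, both regions or levels, and with fry 0 in MEC, LEC and both regions and 6 for levels. With labelled dyes the difference between regions gave 1 gene, and lists passing were 3 in MEC, 3 for the difference and 3 over both regions; reversed in LEC were Ust (0.056), Tmem42 (0.0092), Ctss (−0.10), C1qc (−0.0064), Ctsb (−0.029) and the lists of microglia (−0.039), interferon (−0.033), astrocytes (−0.24, called lower) and cathepsins (−0.075), over both regions cathepsins (−0.0040), and for the difference Tfam (0.029). By file names and labelled dyes lists passing were 2 in MEC, 4 in LEC, 2 for the difference and 3 over both regions, and reversed were immediate early genes in LEC (−0.054) and over both regions (−0.025) and oxidative stress defence over both regions (0.0026). Without replicate 2, 4 lists passed for the difference, and the astrocyte list in LEC had a mean of −0.11. Naglu, 0.02 in the main results, read −0.055 with processed signals, −0.0069 at its dimmer probe and −0.022 by file names. With a single pair left out, genes passing ranged from 0 to 1 in MEC and over both regions, 0 to 0 in LEC, for the difference and for the overlap, and 1719 to 2567 for levels, and lists from 1 to 8 in MEC, 3 to 8 in LEC, 0 to 3 for the difference, 5 to 8 over both regions and 1 to 2 for levels, against 6, 7, 0, 8 and 1 with all pairs. Counts moved by over 1.5 times without LEC replicate 2 (1 gene, Lyz2, in MEC and over both regions, 1762 for levels), MEC replicate 1 (1719 for levels, 1 list for the difference, 2 for levels), MEC replicate 2 (2 lists for the difference, 2 for levels), MEC replicate 3 (1 list in MEC, 1 for the difference), LEC replicate 1 (3 lists for the difference) and LEC replicate 3 (3 lists in LEC, 5 over both regions, 1 for the difference, 2 for levels); the lists that reversed then were mitochondria in MEC (up to 0.020, without MEC replicate 3) and astrocytes in LEC (−0.11 to 0.24, lowest without LEC replicate 2). With the replicate number as a block, whose pairing the labels do not state and the values do not bear out (correlations 0.13, −0.13 and −0.15 across genes between pairs of the same number), genes passing were 0 in MEC, LEC, the difference and both regions and 2391 for levels, lists 7, 5, 0, 8 and 1, and Naglu 0.02. A block of slide or scan day was not run, since each slide holds 1 array and no day both regions. Apart from settings that test fewer genes or samples, the cause was not tested. Over all settings the adjusted p of Lyz2 ranged from 0.000347 to 1.00 in MEC, 0.000398 to 1.00 in LEC and 3.12e-06 to 1.00 over both regions. Each lower end came from the 12 arrays as units, where dye-swapped duplicates enter separately although the pair is the unit of replication. Signal over background limits genes of low expression, as 14.8 to 30.4 percent of spots per array were well above background in Cy5 and 48.2 to 67.9 percent in Cy3.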

Other observations

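The genes in these paragraphs were chosen after their values were seen, from lists fixed before, and no test of an explanation was run on them. Markers of cortical layers and the hippocampal formation differed in level between MEC and LEC captures in both directions, with 8 of 24 higher in MEC and 8 lower over all genes (8 and 11 adjusted over the list alone). Lower in MEC, beside Penk, were Fxyd6, a regulator of the sodium pump, at −1.11 (SE 0.16), the gastrin-releasing peptide gene Grp at −0.998 (SE 0.09, a size set by background with 5 of 12 MEC readings well above it), the thyroid hormone binding protein gene Crym at −0.94 (SE 0.14), calbindin, Calb1, at −0.93 (SE 0.14), the transcription regulator Lmo4 at −0.85 (SE 0.16) and the axon guidance gene Ntng1 at −0.65 (SE 0.15). Higher in MEC were the transcription factor Neurod6 by 1.16 (SE 0.10), Wfs1, a protein of the endoplasmic reticulum, by 0.99 (SE 0.17), the nuclear receptor Nr4a2 by 0.86 (SE 0.16) and Reln, the secreted protein reelin, by 0.62 (SE 0.13). With median centring the genes lower in MEC read −1.72 to −1.17, and Neurod6 read 0.89 and still passed, while Wfs1, Nr4a2 and Reln read 0.42, 0.46 and 0.11 and did not pass. MEC and LEC arrays were scanned on different days, so region and scan cannot be told apart here either.

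Single members of the lists of immediate early genes, postsynaptic receptors and inhibitory neuron markers differed in level, while none of the 3 lists passed camera (adjusted p 0.154, 0.617 and 0.399). Over all genes 6 of 20 immediate early genes passed higher in MEC and 1 lower, 2 and 5 of 25 genes of postsynaptic receptors and scaffolds, and 5 and 1 of 14 inhibitory neuron markers. The immediate early genes Ier5 and Arc were higher in MEC by 1.22 (SE 0.08) and 1.08 (SE 0.10), and with median centring by 0.73 and 0.56, still passing. Gria1, a subunit of the excitatory AMPA receptor, was lower in MEC at −0.63 (SE 0.08) and −1.25 with median centring. Among interneuron genes the serotonin receptor Htr3a was higher in MEC by 1.02 (SE 0.20), which with median centring was 0.43 and did not pass, and somatostatin, Sst, was lower at −0.86 (SE 0.22) and −1.28.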
